A study of Mus musculus with 6 samples.

How the data were processed

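The study measured gene expression in mouse Notch1-driven T-ALL cells with the QuantSeq 3' mRNA kit, which primes on poly(A) tails and sequences the ends of transcripts. Per the labels' protocols, RNA was isolated on columns, and each library was made from 100 ng of total RNA. There were 3 libraries of cells given 25 nM panobinostat for 2 h and 3 of untreated cells, grouped by the treatment named in the labels. Per the submitters' processing notes, the tools were cutadapt 1.9, HISAT2 2.1.0, featureCounts from Subread 1.5.0 and limma, with build mm10. The annotation, strand setting and filters used were not given in the sources used here.

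The authors deposited a single table of log2 values with gene symbols in 13185 rows and 1 column per library. That these are log2 CPM (counts per 1000000 reads), quantile normalized between the libraries, was inferred from the values. Their powers of 2 summed to between 994114 and 994182 in each library, and the sorted values of the libraries lay within 0.05 of their common mean for 94.5% of rows. All columns were mapped to a sample by the names in the table. The row Gm42418, which lies over ribosomal RNA sequence, held 6.83% of all CPM. In 19 rows the symbol had been turned into a date by spreadsheet software, and 1 such name occurred in more than 1 row, so these rows were named nowhere.

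Depth was estimated from ties, since genes with equal read counts share a value in a library. The number of steps between distinct values per CPM was nearly constant up to 300 steps, so that 1 step was taken as 1 read. At 200 steps it gave 5.99, 6.76 and 7.57 reads per CPM in treated libraries 1 to 3, and 7.72, 6.71 and 6.57 in untreated libraries 1 to 3. Reads without molecular identifiers are not independent molecules.

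Genes with a mean log2 of at least 0 over the 6 libraries were tested, which left out 631 rows. A linear model was fitted with limma 3.58.1 (lmFit, then eBayes with a mean-variance trend) in R 4.3.3 on the values as deposited, with Benjamini-Hochberg adjustment and a threshold of 0.05. No pseudocount was added. Gene lists were tested with camera at a preset correlation of 0.01 where at least 5 members were tested, adjusted over the lists. The exact permutation test of expression bins enumerated all assignments of the 6 libraries to 2 groups of 3. Text tables were read with Python 3.11.15 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.

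Before the data were examined, 35 gene lists, the tests, the main alternatives and the rule for named genes were fixed. The rule took the 12 largest rises and 12 largest falls among genes past the threshold, with a mean level at or above the median of the tested genes (4.16) and no overlap between the groups, leaving out predicted genes and pseudogenes. It also took up to 4 members with the smallest adjusted p from each list, and always the HDAC genes, Notch1, Hes1, Dtx1, Nrarp, Myc, Cdkn1a, H1f0, Bcl2l11, Bmf, Bcl2, Mcl1 and Hexim1. It named 167 genes, of which 149 passed the threshold. Hdac9 was not among the tested genes. Members of a list are called measured where they were among the tested genes.

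Gene positions, the GC content of the last 500 bases of transcripts and transcript lengths came from GENCODE release M21 on the same build. By symbol 12945 rows were matched, and 156 by a listed synonym. A further 31 symbols matched several genes and 34 matched none.

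The scripts were tested on data simulated from the means and spreads of the 12554 genes of this comparison, with 200 genes changed. Of 100 genes changed by 1 on the log2 scale 41% were called, and of 100 changed by 0.5 8% were called, while 4 of 12354 unchanged genes were called. The data had 4806 calls, and adjustment is stricter where fewer genes change, so these shares do not give the share of real changes missed. Camera called a shifted list of 20 genes and did not call an unshifted one. Genes were simulated independently of each other, so this check says nothing of lists whose members vary together. Reads recovered from ties lay within 1 of the simulated reads in 100% of values at up to 300 reads.

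Alternatives were another filter, other scalings, other spread models, sample weights, a stricter threshold, other set tests and each library left out in turn. A fit with the replicate number as a block, a pseudocount of 1 on linear values and a test on reads recovered from ties were chosen after seeing the data. The trimmed mean scaling was written for this work on the log2 values and has no precision weights.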

Results

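The data were 6 libraries of 3' mRNA sequencing, in which reads are taken from the polyadenylated end of each transcript, from mouse T-cell acute lymphoblastic leukaemia (T-ALL) cells driven by Notch1. All cells were cultured on plate-bound antibody to CD3 (2.5 ug/mL), which engages the T cell receptor complex, with the T cell growth factor IL-2 at 100 U/mL. In 3 libraries the cells had received 25 nM panobinostat, an inhibitor of histone deacetylases (HDACs), for 2 h, and 3 libraries came from untreated cells. The deposited table held log2 CPM (counts per 1000000 reads) for 13185 gene rows. Estimated from the steps between tied low values, 1 CPM corresponded to between 5.99 and 7.72 reads, which gave between 5990000 and 7720000 reads per library. The labels did not say whether the 3 libraries of a group came from separate cultures or animals. Sample titles gave every library the same replicate number, 1, and differed within a group only in a number after the letter S. The library numbers 1 to 3 used here came from the table's column names. The p-values therefore measure only the spread between these samples, which may be technical. Across genes, Pearson correlations ran from 0.964 to 0.974 within groups and from 0.923 to 0.945 between groups, and no pair of libraries was identical.

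The single comparison of the design asked how 2 h of panobinostat changed gene expression in these leukaemia cells. Genes moved in both directions in nearly equal numbers. Of 12554 genes tested, 2416 rose and 2390 fell in treated cells, and with a change of at least 2-fold 643 rose and 646 fell (limma, Benjamini-Hochberg adjusted p below 0.05). The thioredoxin-binding protein Txnip and Id3, an inhibitor of E-protein transcription factors, rose the most among well-expressed genes. Mlst8, a subunit of the mTOR complexes, and Kmt5b, a histone H4 lysine methyltransferase, fell the most. The median log2 fold change of all tested genes was -0.0052. The values looked quantile normalized between libraries, with library medians of 4.01 to 4.02 log2 CPM. Neither this median nor the near balance of rises and falls could therefore show a shift of all genes one way. In 6459 genes (51.4%) the 3 treated and 3 untreated libraries did not overlap, against 10% by chance. The 4806 calls became 5233 without untreated library 1, which lay nearer the treated libraries than the other untreated libraries did on the first principal component (-25.7 against -48 and -41, treated 35.4 to 43.2).

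Among well-expressed genes whose groups did not overlap, the 12 largest rises spanned log2 fold changes from 1.79 to 2.68. Values after ± beside a log2 fold change are its standard error (SE). Txnip (chromosome 3, 96557957 to 96561883) reached 6.53 ± 0.30 log2 CPM in treated against 3.85 ± 0.81 in untreated libraries (SD, n = 3). Its change was the largest of these (log2 fold change 2.68, SE 0.37, limma adjusted p = 0.00171). Id3 (chromosome 4, 136143497 to 136145755) stood at 6.25 ± 0.31 log2 CPM in treated against 3.67 ± 0.61 in untreated libraries (SD, n = 3) (log2 fold change 2.57, SE 0.29, limma adjusted p = 0.000899). Nr4a1, an orphan nuclear receptor induced by antigen receptor signals, rose from 4.23 to 6.23 log2 CPM (log2 fold change 2.00, SE 0.22, limma adjusted p = 0.000755). The nuclear envelope protein Sun1 rose by 2.08 ± 0.25 (SE), the scaffold gene Grasp by 2.07 ± 0.13, the F-box gene Fbxl12 by 2.07 ± 0.31 and Ccdc115 by 2.02 ± 0.28 on the log2 scale. The palmitoyltransferase gene Zdhhc8 rose by 1.96 ± 0.37, Tmem50b by 1.904 ± 0.12, Susd6 by 1.82 ± 0.31, the PHD finger gene Phf13 by 1.80 ± 0.12 and the RNA-binding protein gene Rbm38 by 1.79 ± 0.26.

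The 12 largest falls spanned -2.59 to -1.85. Mlst8 (chromosome 17, 24473551 to 24479078) was at 3.72 ± 0.16 log2 CPM in treated against 6.31 ± 0.18 in untreated libraries (SD, n = 3) (log2 fold change -2.59, SE 0.13, limma adjusted p = 0.000101). Kmt5b (chromosome 19, 3767421 to 3818303) was at 3.46 ± 0.20 log2 CPM in treated against 5.89 ± 0.26 in untreated libraries (SD, n = 3) (log2 fold change -2.43, SE 0.16, limma adjusted p = 0.0002). The mitochondrial iron-sulphur assembly gene Iba57 changed by -2.28 ± 0.24 (SE), the receptor phosphatase gene Ptpro by -2.19 ± 0.12, Ubxn8 by -2.01 ± 0.14 and Ramp3, an accessory protein of G protein-coupled receptors, by -1.998 ± 0.15. Sh2d2a, which encodes a T cell adaptor protein that binds Lck, changed by -1.97 ± 0.10, the histone acetyltransferase subunit gene Epc2 by -1.90 ± 0.10 and the pseudokinase gene Trib1 by -1.89 ± 0.15. Values for the remaining 3 were Ptp4a1 (-1.89 ± 0.48), Parp11 (-1.85 ± 0.23) and Usp50 (-1.85 ± 0.40). The Ptp4a1 symbol matched several annotated genes, and its call was lost without panobinostat library 1 (-1.83). Its untreated values differed widely (5.10, 7.33 and 5.86 log2 CPM), and without untreated library 2 its log2 fold change was -1.27.

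**Figure D1:**
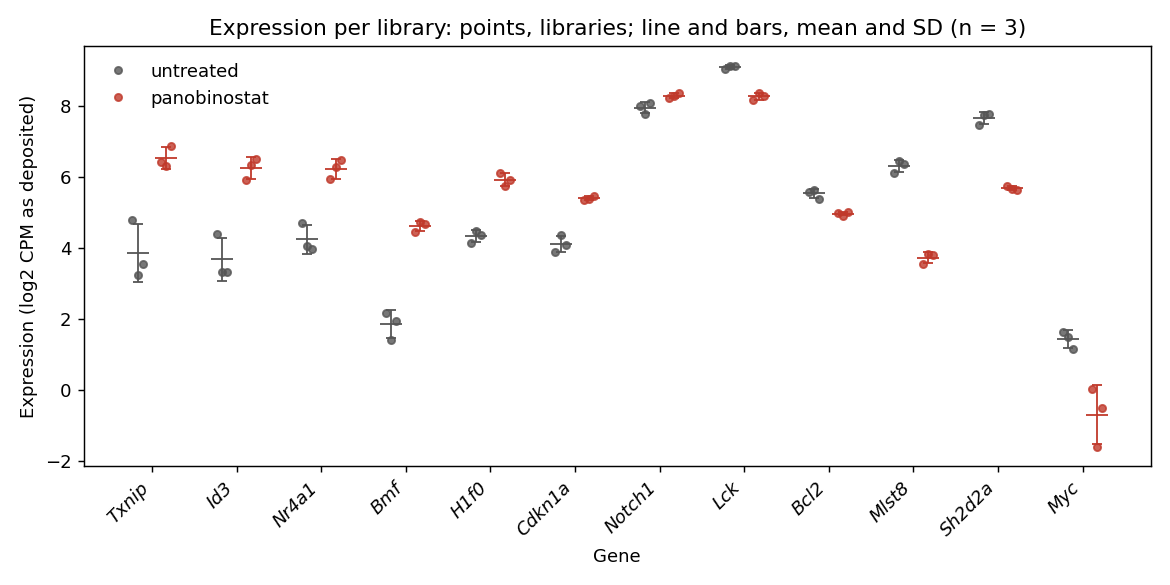
Expression of 12 named genes in log2 CPM as deposited (vertical axis), with 1 point per library, a line at the mean and bars of 1 SD for 3 untreated (grey) and 3 panobinostat (red) libraries. Txnip, Id3, Nr4a1, Bmf, H1f0, Cdkn1a and Notch1 were higher and Lck, Bcl2, Mlst8, Sh2d2a and Myc lower in treated libraries, and untreated library 1 had the highest untreated value of Txnip and Id3.

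Genes reported to respond to HDAC inhibitors in other cells included rises and no falls: 6 rose and 0 fell of 19 measured (6 and 0 adjusted over the list alone, camera adjusted p = 0.0655). Those that rose included Txnip, the linker histone gene H1f0 (5.92 ± 0.18 log2 CPM in treated against 4.32 ± 0.17 in untreated libraries (SD, n = 3); log2 fold change 1.60, SE 0.13, limma adjusted p = 0.00032), the CDK inhibitor genes Cdkn1a (chromosome 17, 29090976 to 29100727; log2 fold change 1.29, SE 0.14, limma adjusted p = 0.00066) and Cdkn2d (0.84 ± 0.10), and the neuronal tubulin gene Tubb3 (1.03 ± 0.24). Hexim1, an inhibitor of the elongation factor P-TEFb, stood at -0.15 ± 0.11 (adjusted p = 0.307). Of the drug's target family, 3 rose and 2 fell of 10 measured (3 and 3 adjusted over the list alone, camera adjusted p = 0.702). Hdac11 (1.08 ± 0.23), Hdac5 (0.91 ± 0.19) and Hdac1 (0.65 ± 0.11) rose, while Hdac7 (-0.68 ± 0.08) and Hdac10 (-0.82 ± 0.26) fell. The Hdac10 call was lost without panobinostat library 1 (-0.66) or 3 (-0.74) and without untreated library 2 (-0.72) or 3 (-0.77). Log2 fold changes that did not pass were Hdac2 (0.04 ± 0.10), Hdac3 (0.21 ± 0.12), Hdac4 (0.16 ± 0.09), Hdac6 (-0.17 ± 0.22) and Hdac8 (-0.37 ± 0.14). Among histone genes 4 rose and 0 fell of 22 measured (4 and 0 adjusted over the list alone, camera adjusted p = 0.0701). The rises were those of H1f0, Hist1h1e (0.79 ± 0.13), H2afv (0.44 ± 0.10) and H3f3b (0.31 ± 0.06). In a wider set taken after the data were seen, the 67 tested genes whose symbols start with Hist, 3 rose and 9 fell. Their median log2 fold change was 0.0163 (camera adjusted p = 0.796), so the reads of this wider set did not go one way. The kit primes on poly(A) tails, so histone transcripts without such a tail were not targeted. Only 4 of the neuronal genes held silent by the repressor REST in many tissues were measured, too few for a list test. Of these, 3 rose and 0 fell (3 and 0 adjusted over the list alone), namely Syt11 (2.103 ± 0.26), Tubb3 and Map2 (0.77 ± 0.22). The Map2 call was lost in 4 of the 6 fits with 1 library left out (0.62 to 0.784 in these).

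Genes of the BCL2 family, which control mitochondrial apoptosis, changed in both classes. In the pro-apoptotic class 5 rose and 1 fell of 8 measured (5 and 1 adjusted over the list alone, camera adjusted p = 0.244). Bmf (chromosome 2, 118528757 to 118549687) rose from low expression, at 4.62 ± 0.14 log2 CPM in treated against 1.84 ± 0.39 in untreated libraries (SD, n = 3) (log2 fold change 2.78, SE 0.22, limma adjusted p = 0.00027). Bid (1.72 ± 0.22), Bbc3, which encodes PUMA (0.62 ± 0.13), and Bcl2l11, which encodes BIM (0.35 ± 0.08), rose as well, whereas the effector gene Bak1 fell (-1.04 ± 0.15). The Bcl2l11 call was lost without panobinostat library 3 (0.34) or untreated library 3 (0.32). In the pro-survival class 0 rose and 4 fell of 6 measured (0 and 4 adjusted over the list alone, camera adjusted p = 0.0541). The falls were those of Bcl2 (-0.58 ± 0.10), Bcl2l1 (-0.84 ± 0.15), Bcl2a1b (-0.79 ± 0.17) and Bcl2a1d (-0.87 ± 0.16). Mcl1 stood at -0.06 ± 0.09 (adjusted p = 0.608). The Bcl2a1 genes are near-identical copies, so the split of reads between them is uncertain. Among death receptors, caspases and IAPs 3 rose and 6 fell of 16 measured (5 and 8 adjusted over the list alone, camera adjusted p = 0.629). The death receptor gene Fas rose from a low level of 0.43 to 2.57 log2 CPM (2.14 ± 0.29), and Diablo rose by 0.65 ± 0.10. Falls included those of the caspase-8 inhibitor gene Cflar (-1.15 ± 0.13) and Ripk1 (-1.16 ± 0.14). Among p53 target genes 7 rose and 1 fell of 15 measured (8 and 1 adjusted over the list alone, camera adjusted p = 0.067). Cdkn1a, Bbc3, Btg2 (0.57 ± 0.08) and Trp53inp1 (0.52 ± 0.08) rose and the p53 ubiquitin ligase gene Mdm2 fell (-0.66 ± 0.09).

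Among T cell receptor signalling genes 0 rose and 12 fell of 21 measured (0 and 13 adjusted over the list alone, camera adjusted p = 0.0359). This was the only one of 32 lists past the threshold with camera's preset correlation, and 0 passed with an estimated correlation (adjusted p = 0.301 for this list). Its call was also lost without panobinostat library 2 (adjusted p = 0.0559) or 3 (0.0506) and without untreated library 1 (0.0501). In 4 of the other 9 splits of the 6 libraries into 3 and 3, between 1 and 5 lists passed the same preset test. The kinase gene Lck (chromosome 4, 129548344 to 129573641) was at 8.27 ± 0.10 log2 CPM in treated against 9.09 ± 0.05 in untreated libraries (SD, n = 3) (log2 fold change -0.82, SE 0.08, limma adjusted p = 0.000425). The adaptor gene Lcp2 changed by -1.49 ± 0.09, the kinase gene Prkcq by -1.32 ± 0.16 and the costimulatory receptor gene Cd28 by -0.91 ± 0.08. Among T cell activation and effector genes 2 rose and 8 fell of 19 measured (2 and 10 adjusted over the list alone, camera adjusted p = 0.0541). Il2ra, the alpha chain of the IL-2 receptor (-1.20 ± 0.12), the costimulatory receptor gene Tnfrsf18 (-0.99 ± 0.12) and the chemokine gene Ccl4 (-1.05 ± 0.13) fell, while the transcription factor gene Irf4 rose (1.36 ± 0.11). Of NF-kB target genes 3 rose and 8 fell of 17 measured (3 and 9 adjusted over the list alone, camera adjusted p = 0.0541). The NF-kB subunit genes Nfkb2 (-1.01 ± 0.16) and Relb (-0.99 ± 0.09), Bcl3 (-1.12 ± 0.13) and Cd83 (-0.75 ± 0.14) were among those that fell. Immediate early genes, induced within minutes of stimulation, went both ways: 9 rose and 3 fell of 26 measured (10 and 5 adjusted over the list alone, camera adjusted p = 0.153). Nr4a1, Nr4a2 (0.84 ± 0.12) and Egr1 (0.79 ± 0.09) rose and Nr4a3 fell (-1.13 ± 0.13). Among cytokine receptors, JAK, STAT and SOCS genes 5 rose and 5 fell of 22 measured (5 and 6 adjusted over the list alone, camera adjusted p = 0.92). Stat3 (0.98 ± 0.11) and Pim3 (0.76 ± 0.10) rose, and Il7r (-2.32 ± 0.33) and Il21r (-1.16 ± 0.15) fell.

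Thymocyte and T-ALL transcription factors were divided, with 5 rose and 11 fell of 26 measured (6 and 12 adjusted over the list alone, camera adjusted p = 0.067). The antagonists of E proteins split, Id3 rising and Id2 falling (-1.54 ± 0.09). Tcf7, a factor of early T cells, rose (1.27 ± 0.14) while Gata3 (-1.40 ± 0.14) and Myb (-0.77 ± 0.07) fell. Of the Notch1 target genes, 2 rose and 6 fell of 16 measured (2 and 7 adjusted over the list alone, camera adjusted p = 0.246). Notch1 itself rose slightly (8.29 ± 0.08 log2 CPM in treated against 7.95 ± 0.16 in untreated libraries (SD, n = 3); log2 fold change 0.34, SE 0.10, limma adjusted p = 0.0272), and this call was lost without panobinostat library 2 (0.34) or 3 (0.30) or untreated library 2 (0.25). The feedback inhibitor gene Nrarp rose (0.68 ± 0.11), and Trib2 (-1.18 ± 0.08), Il7r and Il2ra fell. Hes1 stood at 0.58 ± 0.25 (adjusted p = 0.102) and passed without untreated library 1 (0.89). Dtx1 stood at 0.08 ± 0.09. Myc (chromosome 15, 61985391 to 61990374) was low in these libraries and fell, at -0.71 ± 0.84 log2 CPM in treated against 1.43 ± 0.25 in untreated libraries (SD, n = 3) (log2 fold change -2.13, SE 0.48, limma adjusted p = 0.0107). Genes driven by Myc and of ribosome biogenesis did not pass when compared with other genes: 11 rose and 5 fell of 37 measured (11 and 5 adjusted over the list alone, camera adjusted p = 0.328). Rrp9 (1.08 ± 0.14), Wdr74 (1.104 ± 0.15), Utp4 (0.74 ± 0.08) and Nolc1 (0.61 ± 0.07) were among those that rose. Of the ribosomal protein genes, many of which share reads with pseudogenes, 23 rose and 3 fell of 85 measured (20 and 3 adjusted over the list alone, camera adjusted p = 0.197). Rps2 (1.37 ± 0.20) and Rpl22l1 (0.81 ± 0.07) rose.

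Among G2 and M phase genes 1 rose and 9 fell of 22 measured (2 and 9 adjusted over the list alone, camera adjusted p = 0.0701). The called falls included Plk1 (-0.87 ± 0.07), Mki67 (-0.81 ± 0.08), Cdc20 (-0.72 ± 0.11) and Hmmr (-0.47 ± 0.09). Among S phase genes 6 rose and 10 fell of 23 measured (7 and 10 adjusted over the list alone, camera adjusted p = 0.417). The replication licensing gene Cdt1 (-0.75 ± 0.08) and the nucleotide synthesis genes Tyms (-0.80 ± 0.11) and Rrm2 (-0.54 ± 0.07) fell, and Gins2 rose (0.84 ± 0.10). For cyclins, CDKs and CDK inhibitors 5 rose and 5 fell of 19 measured (5 and 6 adjusted over the list alone, camera adjusted p = 0.873). Cdkn1a, Cdkn2d and Cdkn2a (0.68 ± 0.10) rose and Cdkn2c fell (-0.72 ± 0.12). Among DNA repair genes 5 rose and 3 fell of 23 measured (5 and 2 adjusted over the list alone, camera adjusted p = 0.248). Rad54l (1.47 ± 0.19), Parp1 (0.48 ± 0.09) and Brca1 (0.45 ± 0.09) rose and Fancd2 fell (-0.49 ± 0.11).

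Among acetyltransferases, bromodomain readers and elongation factors 4 rose and 7 fell of 20 measured (5 and 7 adjusted over the list alone, camera adjusted p = 0.157). The acetyltransferase genes Kat5 (-1.46 ± 0.10), Kat7 (-1.20 ± 0.11) and Crebbp (-1.19 ± 0.07) fell, and the elongation factor gene Ell rose (2.15 ± 0.21). Among polycomb, DNA methylation and histone methylation genes 6 rose and 8 fell of 26 measured (6 and 8 adjusted over the list alone, camera adjusted p = 0.656). The polycomb genes Bmi1 (-0.98 ± 0.09) and Ezh2 (-0.47 ± 0.07) fell, and the H3K4 demethylase genes Kdm5b (1.37 ± 0.16) and Kdm5a (0.55 ± 0.07) rose.

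Of the following lists none passed with camera. Among cholesterol synthesis genes 9 rose and 2 fell of 18 measured (9 and 2 adjusted over the list alone, camera adjusted p = 0.0541). The enzyme genes Fdft1 (1.05 ± 0.09), Mvd (1.05 ± 0.19) and Idi1 (0.84 ± 0.14) rose. Among glycolysis genes 2 rose and 7 fell of 18 measured (2 and 8 adjusted over the list alone, camera adjusted p = 0.116). The lactate exporter gene Slc16a3 (-1.44 ± 0.11), Pfkl (-1.15 ± 0.17) and Gpi1 (-0.47 ± 0.08) fell. Among unfolded protein and integrated stress response genes 4 rose and 5 fell of 17 measured (4 and 5 adjusted over the list alone, camera adjusted p = 0.92). The cystine transporter gene Slc7a11 (-2.08 ± 0.14) and Trib3 (-1.88 ± 0.33) fell and the chaperone gene Hyou1 rose (1.03 ± 0.09). Heat shock genes gave 3 rose and 1 fell of 14 measured (3 and 0 adjusted over the list alone, camera adjusted p = 0.326). Hsf1 (0.94 ± 0.19) and Hspe1 (0.57 ± 0.09) rose. Of mitochondrially encoded genes 2 rose and 1 fell of 24 measured (1 and 1 adjusted over the list alone, camera adjusted p = 0.8). The cytochrome b gene mt-Cytb rose (0.47 ± 0.08). Among interferon-stimulated genes 4 rose and 10 fell of 30 measured (4 and 10 adjusted over the list alone, camera adjusted p = 0.067). Gbp3 (-1.48 ± 0.18), Parp14 (-1.20 ± 0.13), Irf9 (-0.82 ± 0.10) and Dtx3l (-0.81 ± 0.09) fell. In MHC and antigen presentation 4 rose and 5 fell of 20 measured (4 and 5 adjusted over the list alone, camera adjusted p = 0.92). Tap2 rose (0.98 ± 0.21), and the class II genes Cd74 (-0.82 ± 0.14) and H2-Eb1 (-0.39 ± 0.09) fell. Median and mean log2 fold change differed in sign for the stress response list (0.0945 and -0.0814), the JAK and STAT list (-0.0675 and 0.00511), the polycomb list (-0.0433 and 0.0184) and the cyclin list (-0.028 and 0.118).

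**Figure D2:**
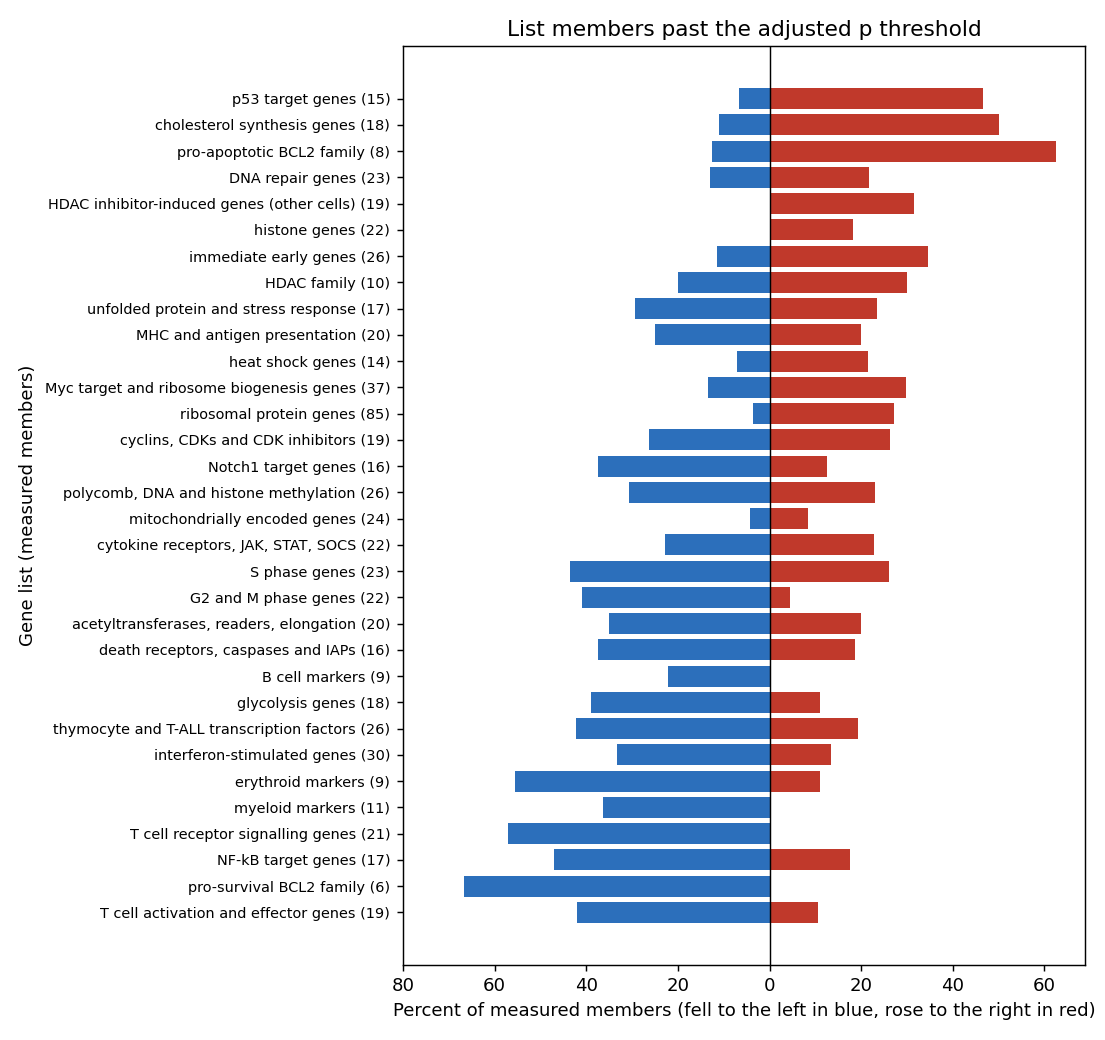
Share of measured members past the adjusted p threshold in each of 32 gene lists (horizontal axis, percent; red to the right rose, blue to the left fell), with the number of measured members in brackets and lists ordered by median log2 fold change. T cell receptor signalling genes had 12 falls and 0 rises among 21 members, and p53 target genes 7 rises and 1 fall among 15.

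Transcripts of other blood lineages were present and several fell with treatment. Among erythroid markers 1 rose and 5 fell of 9 measured (1 and 5 adjusted over the list alone, camera adjusted p = 0.227). The alpha globin gene Hba-a1 was at 10.96 ± 0.07 log2 CPM in treated against 11.33 ± 0.20 in untreated libraries (SD, n = 3) (-0.37 ± 0.11), and the beta globin gene Hbb-bs rose (0.35 ± 0.10). The erythroid factor gene Klf1 (-1.31 ± 0.16) and Slc4a1 (-0.46 ± 0.11) fell. Each globin gene has a near-identical copy, and these globin calls were lost in 4 (Hbb-bs, 0.35 to 0.37) and 5 (Hba-a1, -0.39 to -0.28) of the 6 fits with 1 library left out. The Slc4a1 call was lost without panobinostat library 2 (-0.41) or 3 (-0.44) or untreated library 3 (-0.36). Among myeloid markers 0 rose and 4 fell of 11 measured (0 and 5 adjusted over the list alone, camera adjusted p = 0.0541). Those were S100a8 (-0.39 ± 0.08), Lyz2 (-0.62 ± 0.11), Mpo (-0.52 ± 0.10) and Csf1r (-1.35 ± 0.36). The Csf1r call was lost without panobinostat library 1 (-1.0) or 3 (-1.38) and without untreated library 2 (-1.09) or 3 (-1.38). The median myeloid marker was between 2.19 and 2.66 log2 CPM in treated and between 2.83 and 3.46 in untreated libraries. Among B cell markers 0 rose and 2 fell of 9 measured (0 and 2 adjusted over the list alone, camera adjusted p = 0.271). The falls included that of Cd79b (-0.97 ± 0.23). Of 3 measured NK cell markers 0 rose and 0 fell (0 and 0 adjusted over the list alone), with values of Nkg7 (0.12 ± 0.34), Gzma (-0.27 ± 0.13) and Tbx21 (-0.54 ± 0.28). Of 3 stromal and endothelial markers 0 rose and 1 fell (0 and 1 adjusted over the list alone), Pecam1 (-0.56 ± 0.15), whose call was lost without panobinostat library 1 (-0.44) or untreated library 3 (-0.57).

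Quantile normalization by the authors holds the distance between strongly and weakly expressed genes alike between libraries, so the values by level say nothing of a change with level or of total RNA. Across 5 bins of mean level the median log2 fold change lay between -0.03 and 0.0106. The share of genes called rose from 18.2% in the lowest bin to 46.8% in the highest, while the median standard error fell from 0.376 to 0.0932. The mean distance between the highest and lowest bin was 6.39 log2 units in treated and 6.38 in untreated libraries (exact permutation test, two-sided p = 0.4, n = 3 against 3, smallest possible 0.1).

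Positions are those of GENCODE release M21 on mm10 and give the span of the whole gene. Reads of overlapping genes were not told apart with certainty, since the strand setting of the counting was not given. Among the genes named, exons overlapped those of another annotated gene for Rbm38 with Gm14453 and Gm20490, Txnip with Gm15441, Sun1 with 4930520M14Rik, Fbxl12 with Ubl5, Ccdc115 with Gm28306, Mlst8 with Bricd5, Usp50 with Gm10774, Kmt5b with Gm16066, Ramp3 with Gm11978, H1f0 with Gm49544, Cdkn1a with AC167363.2, Hdac11 with Gm14573 and Gm44002, Hdac5 with Mir8101, Hdac7 with Slc48a1, Hdac4 with Gm26720, Hist1h1e with Gm11398 and Hist1h2be, Map2 with Gm10558, Bid with Bcl2l13, Bak1 with Ggnbp1, Bcl2 with D630008O14Rik, Bcl2a1b with Gm29094, Diablo with Gm49027 and AC157931.1 and B3gnt4, Ripk1 with Gm17084 and Serpinb6a, Lck with Mir8119, Lcp2 with 4930469K13Rik, Tnfrsf18 with Gm16008, Nfkb2 with AC114539.1 and Psd, Bcl3 with Gm16175, Stat3 with Stat5a, Gata3 with 9230102O04Rik and Gm13256, Myb with Gm26577, Notch1 with 0610009E02Rik and Gm13568, Nrarp with Gm38287, Rrp9 with Parp3, Rps2 with Snora64 and Snhg9, Rpl22l1 with Gm33051, Plk1 with Gm44985, Cdc20 with Elovl1, Gins2 with Gse1, Rad54l with Lrrc41, Parp1 with Mir6904, Fancd2 with Fancd2os, Kat5 with Rnaseh2c, Ezh2 with Gm26625, Kdm5a with Ccdc77, Fdft1 with Ctsb, Idi1 with Gm48574, Gpi1 with Gm26762, Hspe1 with Hspd1, Parp14 with Gm49730, Irf9 with Rnf31, Dtx3l with Parp9, Tap2 with Gm15821 and Gm20496, Cd74 with Mir5107, Mpo with Gm11505 and Csf1r with Hmgxb3.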

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

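Chosen only after the data were seen were the replicate block, the pseudocount of 1 on linear values and the reads recovered from ties. With all libraries, the number of genes called ran from 4001 to 4968 over the alternative fits, and array weights gave 6107. At an adjusted p of 0.01 the count was 2513. Of the 4806 called genes 0 changed sign in these fits or with a library left out. Each library left out in turn gave from 3299 calls (without panobinostat library 3) to 5233 (without untreated library 1), and from 1072 to 1531 with at least a 2-fold change. The count with at least a 2-fold change was 652 with a mean log2 of at least 3, where 8489 genes were tested. Among all 12554 genes it was 910 with the pseudocount of 1 and 1563 with array weights. Further scalings (4801 to 4816 calls) were applied to values already quantile normalized, so they could hardly move the calls and say little of stability. Among 8030 genes at up to 300 reads, limma called 2594 from recovered reads and 2609 from the deposited values, 2546 of them in both with the same sign.

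No label pairs the libraries, and only the table's column names share numbers. Deviations from the group means correlated at -0.0444, 0.104 and -0.0108 for equal numbers, so the numbers were not taken as pairs. Treated library 3 correlated most with untreated library 1 (0.152). With the number as a replicate block 4148 genes were called, and 4 lists passed, among them T cell activation, cholesterol synthesis and myeloid markers (adjusted p = 0.0478 each). With an estimated correlation, without the block, these 3 did not pass (0.301, 0.301 and 0.416).

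With camera, 2 lists passed with a mean log2 of at least 3, 2 without the trend and 4 with array weights, and leaving out a library gave 0 (without panobinostat library 2 or 3) to 7 lists (without panobinostat library 1 or untreated library 2). With an estimated correlation 0 passed, against 1 with the preset one, T cell receptor signalling (adjusted p = 0.301 when estimated). Cholesterol synthesis passed with the higher filter (adjusted p = 0.0325) and with array weights (0.0467). T cell activation genes passed without the trend (0.045) and with array weights (0.0467), as myeloid markers did with array weights (0.0467), all with the preset correlation. Direction turned with the higher filter for MHC genes (adjusted p = 0.983) and stress response genes (0.987), with array weights for JAK and STAT genes (0.903) and with fry for MHC genes (0.748). Without each library in turn, camera adjusted p values ran 0.0443 to 0.102 for genes known to rise with HDAC inhibitors in other cells, 0.626 to 0.954 for MHC and antigen presentation, 0.0418 to 0.102 for pro-survival BCL2 family, 0.0485 to 0.174 for p53 target genes, 0.0418 to 0.291 for G2 and M phase genes, 0.0418 to 0.104 for T cell activation and effector genes, 0.762 to 0.997 for cytokine receptors, JAK, STAT and SOCS genes, 0.0153 to 0.0559 for T cell receptor signalling genes, 0.0418 to 0.164 for thymocyte and T-ALL transcription factors, 0.0418 to 0.104 for NF-kB target genes, 0.336 to 0.997 for polycomb, DNA methylation and histone methylation genes, 0.0418 to 0.0875 for cholesterol synthesis genes, 0.0391 to 0.0559 for myeloid markers and 0.184 to 0.997 for mitochondrially encoded genes. Direction turned for the polycomb list without untreated library 1 (0.997), for MHC genes without panobinostat library 2 (0.865) or untreated library 2 (0.887), for JAK and STAT genes without panobinostat library 1 (0.864) or untreated library 2 (0.933) and for mitochondrially encoded genes without panobinostat library 2 (0.99). Fry, which asks whether a list's genes move on balance one way and compares them with no other genes, passed 24 lists. Its adjusted p was 0.00117 for acetyltransferases, bromodomain readers and elongation factors, 0.0026 for genes known to rise with HDAC inhibitors in other cells, 0.00466 for Notch1 target genes, 0.017 for Myc target and ribosome biogenesis genes, 0.00685 for interferon-stimulated genes, 0.00917 for pro-apoptotic BCL2 family, 0.000334 for pro-survival BCL2 family, 0.0144 for death receptors, caspases and IAPs, 0.00985 for p53 target genes, 0.0394 for S phase genes, 0.0162 for G2 and M phase genes, 0.00917 for immediate early genes, 0.000176 for T cell activation and effector genes, 0.00571 for thymocyte and T-ALL transcription factors, 0.00148 for NF-kB target genes, 0.0292 for heat shock genes, 0.0237 for histone genes, 0.00917 for glycolysis genes, 0.000694 for cholesterol synthesis genes, 0.0111 for B cell markers, 0.0111 for myeloid markers, 0.0144 for erythroid markers and 0.00965 for ribosomal protein genes. For T cell receptor signalling genes, the only list past camera's preset test with all libraries in the main fit, the fry adjusted p was 0.000176. The causes were not tested.

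For the difference in median log2 fold change between the highest and lowest bin of level, array weights gave 0.0447, the pseudocount 0.0299 and leaving out a library -0.00438 (without panobinostat library 2) to 0.0579 (without untreated library 1). With the level from untreated library 1, 2 or 3 alone, and the fold from the other untreated libraries, it was -0.0921, -0.182 and -0.171.

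Of 167 named genes 149 were called, and 15 of these lost their call without some library. Among genes not called, the sign turned for Hdac6 with array weights (0.0186). With a library left out, log2 fold changes ran from -0.375 to 0.0544 for Hdac6, from -0.0361 to 0.11 for Hdac2, from -0.0166 to 0.129 for Dtx1 and from -0.0293 to 0.405 for Nkg7. The planned pseudocounts, meant for a table of linear values, and a count test with other tools were not run, since the table held log2 values. Only the unplanned pseudocount of 1, on values turned back to linear, was fitted (4851 genes called). Camera has no robust form.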

Other observations

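The groups of genes in this paragraph were chosen after the data were seen, by testing each of 95 symbol stems shared by at least 12 tested genes. Genes for interleukins and their receptors (stem Il) gave 2 rises and 13 falls among 32 tested, with a median log2 fold change of -0.537 (camera adjusted p = 0.0453). Genes for CD surface antigens (stem Cd) gave 3 rises and 27 falls among 65, with a median of -0.347 (adjusted p = 0.0453). These were the 2 stems past the threshold with the preset correlation, and 0 passed with an estimated one (adjusted p = 0.715 for both). The next smallest adjusted p was that of the stem Sec (11 rises and 2 falls of 23, adjusted p = 0.114). A test of zinc finger genes alone was run first and dropped, since the family had been noticed in the same data.

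Biotypes were also compared after the data were seen. Some classes of non-coding transcripts had more falls than rises, while protein-coding genes were balanced. Of 130 lincRNAs 10 rose and 29 fell, and of 108 antisense transcripts 4 rose and 19 fell, against 2240 rises and 2197 falls among 10633 protein-coding genes. Other classes had more rises, such as annotated miRNA genes (10 rises and 4 falls of 39). Reads at miRNA genes were not told apart from those of overlapping genes, such as Lck with Mir8119, so these counts do not show that miRNAs rose. The strand setting of the counting was not given, so reads of antisense transcripts and of their partner genes were not separated with certainty. These counts were not tested against each other. Whether long genes fell more than short ones was tested: the median log2 fold change of the longest 20% of protein-coding genes minus that of the shortest 20% was 0.0144, below the difference of 0.1 set beforehand.

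Tests of the recovered reads, of the 2-fold count under other splits and of the lineage markers were chosen after their results were seen, the others before. In the 10 splits of the 6 libraries into 3 and 3, 1 split, the real one, reached 4806 genes (1289 with at least a 2-fold change) and the highest other 0, but 10 splits are too few for a share under 0.05. For gene lists, 5 of the 10 splits passed at least as many lists as the real one (1), up to 5. Removing trends with GC content and transcript length from every library left 4833 calls, against 4771 before among the same 12477 genes, 4588 of them shared with the same sign, which argues against such trends as the cause. Calls from reads recovered without quantile normalization (2594 against 2609 among 8030 genes) argue against the authors' normalization as the cause for these genes only. They were 64% of the tested genes, and genes with more reads were not covered. The comparison of recovered reads did not test whether all genes shifted one way.

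Untreated library 1 lay nearer the treated libraries. Its shift along the treatment axis was 0.189 of the treatment difference, against -0.12 and -0.0694 for untreated libraries 2 and 3. Each library was measured against the other untreated ones, so the negative values follow in part from library 1. Greater depth is argued against by a shift of 0.251 among the 20% of genes with the highest level, and GC content or length by 0.183 after their trends were removed (0.19 before). A candidate explanation is treated RNA in this library: genes called without it implied a share of 0.238 from rising and 0.286 from falling genes, a difference of -0.0473 (bootstrap 95% interval -0.0859 to -0.00714), just inside the bound of 0.05 set beforehand, but among genes changed by more than 2 on the log2 scale the shares were 0.197 and 0.325, past that bound. The same differences were 0.0571 and -0.0575 in untreated libraries 2 and 3. Their shares lay between -0.0804 and 0.042, with library 1 in the reference of each. The test is therefore coarse, and treated RNA in library 1 stays open as an explanation. A culture partly along the same path would look alike, and no biological explanation was tested.

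Some transcripts of other blood lineages were abundant, Hba-a1 at 11.33 and S100a8 at 9.91 log2 CPM in untreated libraries, and most called lineage markers fell. The median marker in untreated libraries was at 6.11 to 6.46 log2 CPM for erythroid markers. It was at 2.83 to 3.46 for myeloid and 3.59 to 3.79 for B cell markers, below the median of the tested genes (4.16). Levels within the B cell list differed widely: Ighm lay 4.69 log2 units above Cd79b in untreated libraries and 5.73 above it in treated ones. A smaller share of red blood cells as the whole cause is argued against by markers that moved apart: under 1 common shift a share of 1e-04 of simulations, the smallest possible here, spread as widely. For B cell markers this share was 0.0087, close to the bound of 0.01, so a smaller share of B cells is only weakly argued against. For myeloid markers it was 0.031, which leaves a smaller share of these cells open, and a change of expression within any of these cells stays open as well. Whether panobinostat acted on such cells directly was not tested.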
